A study of Mus musculus with 6 samples.

How the data were processed

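RNA sequencing was carried out on microglia sorted from the hippocampus of 10-month-old male mice that lack progranulin (gene Grn, strain B6.129S4(FVB)-Grntm1.1Far/Mmja). Per the labels' protocols, hippocampi of 2 mice were pooled for each sample, the tissue was dounced, myelin was removed on Percoll, and about 10000 live cells positive for CD11b and low for CD45 were collected by flow cytometry. BODIPY, a dye that stains neutral lipids, parted these cells into a lipid droplet-low and a lipid droplet-high fraction, called BODIPY-low and BODIPY-high here. Each group has 3 libraries, and no wild-type library was analysed here. Per the labels' protocols, cDNA was made with the SmartSeq v4 kit from RNA with an integrity number above 9, libraries were made with Nextera XT, and both ends were read over 100 bases.

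Per the submitters' processing notes and the series' design text, FastQC 0.11.4 and STAR 2.5.3a were used, reads per gene came from STAR's own gene counting, and DESeq2 with standard settings made the authors' comparison. The design text names the mouse build mm10, while the processing notes list mm9 beside it. The gene annotation and the strand column that was counted are not given in the sources used here, and the kits named do not mark strand, so reads from a gene and from an overlapping gene on the other strand cannot be told apart.

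The deposited values are a signal made by the authors from read counts: each count was divided by 1 size factor per library. Whole reads could be recovered, because every nonzero value was a whole multiple of the smallest value in its library. At a tolerance of 0.01 read, 100% of the values came out whole, and the largest distance from a whole number was 0.00116. Size factors computed from the recovered reads by the median of ratios differed from those behind the deposited values by a relative difference of at most 5.11e-10 in the 6 libraries. The table holds 16179 genes, the lowest of which has 3 reads in all. A date stands in place of the symbol of 24 genes, and 2 dates name 2 genes each, all kept under the name given. Of all symbols, 15532 (96.0%) matched the GENCODE M21 annotation of GRCm38, the assembly of mm10, which gave coordinates, transcript lengths and GC content. Protein genes of the mitochondrial genome are absent from the table, so that list has no result.

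Recovered reads came to between 24982215 and 34899425 per library. Shares of reads for single libraries carry 95% exact Clopper-Pearson intervals, and for genes with 3 or fewer reads in a group the fold is either a lower bound against a floor of 3 reads over the group or a ratio of pooled reads with an exact interval. These intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

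The test of each gene was limma 3.58.1 (R 4.3.3, trended variance, two-sided) on log2(value + 1), with no block, for the 12821 genes with a mean of at least 10 over the 6 libraries. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2(value + 1) scale, BODIPY-high minus BODIPY-low, and the pseudocount of 1 shrinks the change of genes with low values. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives. DESeq2 gave no adjusted p for 5 of the tested genes, which count as not called by it.

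Gene lists were tested with camera from limma, at a preset correlation between genes of 0.01, over the 30 lists with at least 5 tested genes and with Benjamini-Hochberg adjustment over them. An estimated correlation and fry, which asks whether a list's genes move one way without comparing them with other genes, were run beside it. There were 20 lists of biological themes, 13 of markers of cell types, and 3 defined by symbol pattern (cytosolic ribosomal proteins, nuclear genes of the respiratory chain, and protein genes of the mitochondrial genome). The themes were lipid droplets, cholesterol synthesis, targets of the liver X receptor with fatty acid synthesis, fatty acid oxidation, fatty acid uptake, lysosome, endosomal trafficking, disease-associated and homeostatic microglia, interferon response, cytokines with NF-kB, oxidative stress, phagocytosis receptors, complement, antigen presentation, immediate early and heat shock genes, endoplasmic reticulum stress, cell cycle, glycolysis, and mTOR with autophagy. The cell types were neuron, astrocyte, oligodendrocyte, oligodendrocyte precursor, endothelium, mural cell, border macrophage, monocyte, neutrophil, T and NK cell, B cell, erythroid cell, and choroid plexus with ependyma. The lists rest on textbook knowledge, and none was chosen on these libraries.

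The groups, the lists, the tests, the rule for naming genes and most alternatives were set before the data were examined. The rule names Grn and Plin2. It adds the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (predicted and clone names left out). From each theme or pattern list it takes up to 4 called members by size of change or, where no member was called, the 2 with the smallest p. From each cell type list it takes only the 2 most abundant members, called or not, so other called members of these lists can go unnamed. Alternatives covered the replicate number as a block, each library left out in turn, the pseudocount, the filter on low values, 3 further scalings, the variance model, the count tests, the threshold and the kind of list test. A further 5 alternatives were added after the data were seen.

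The tests tried on simulated data were limma, edgeR, DESeq2 and camera at its preset correlation. The data were drawn from the real means, depths and spread of 12692 genes. Neither fry nor camera with an estimated correlation was tried this way. Of 50 genes changed 1.5-fold, limma recovered 32%, and of 50 each changed 2-fold, 4-fold and 8-fold it recovered 66%, 82% and 90%, with 10 calls among 12492 unchanged genes. Camera called 5 of 5 simulated lists shifted by 0.5 on the log2 scale and 0 of 15 unshifted ones. Each gene was simulated independently, so this cannot show how often camera errs where the genes of a list move together. In the real lists the estimated correlation ran from -0.04 (lipid droplets) to 0.89 (choroid plexus and ependyma), with 0.53 for the respiratory chain. Groups of 3 against 3 allow an exact two-sided permutation p no lower than 0.1, so single values that were tested this way could not pass a threshold of 0.05.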

Results

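The series measured gene expression in microglia from the hippocampus of progranulin knockout mice, sorted by their content of neutral lipid. It asks how lipid droplet-high microglia differ from lipid droplet-low microglia in these mice. Each of the 2 groups has 3 libraries. Recovered reads came to 25014007, 25942652 and 29788094 in BODIPY-low replicates 1, 2 and 3, and to 30285045, 24982215 and 34899425 in BODIPY-high replicates 1, 2 and 3. The groups overlapped in depth (exact two-sided permutation p = 0.5, smallest possible 0.1). Genes detected per library numbered 14441 ± 121 in BODIPY-low and 14734 ± 47.6 in BODIPY-high libraries (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible), and all 3 BODIPY-high libraries lay above all 3 BODIPY-low ones. Each library comes from a pool of 2 mice, and the labels do not say whether a low and a high library share a pool. All p-values measure only the spread between these 6 libraries.

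Grn, which encodes progranulin, is the gene targeted in these mice (GRCm38 chromosome 11, 102430315 to 102437048). Normalised read counts of Grn were 416, 625 and 990.1 in BODIPY-low replicates 1, 2 and 3, and 468, 657 and 1614 in BODIPY-high replicates 1, 2 and 3. The groups overlapped (exact two-sided permutation p = 0.6, smallest possible 0.1), and limma gave a log2 fold change of 0.31 (SE 0.41, adjusted p = 0.675). In both groups the values rose from replicate 1 to 3, and each BODIPY-high value exceeded the BODIPY-low value of its number. Both tests are unpaired and do not use that order. Where along the gene the Grn reads lie was not analysed here, so the values cannot check the deletion. Exons of Grn also overlap Fam171a2 on the other strand, and how reads in that overlap were counted is not known.

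Plin2, the main perilipin of lipid droplets in many cells (chromosome 4, 86648386 to 86670060), had 1665 ± 319 and 1787 ± 287 normalised reads in BODIPY-low and BODIPY-high libraries (SD, n = 3 each), and limma gave a log2 fold change of 0.11 (SE 0.15, adjusted p = 0.708). Among 21 tested lipid droplet genes only Plin3, a perilipin that moves between cytosol and droplets, rose, from 619 ± 61.6 to 1154 ± 86.2 (log2 fold change 0.90, SE 0.13, adjusted p = 0.00117). The count adjusted over the list alone was also 1, and the lipid droplet list had a median log2 fold change of -0.04 (camera adjusted p = 0.680).

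BODIPY-high libraries differed from BODIPY-low libraries in 1706 of 12821 tested genes. Of these, 1255 were higher and 451 lower in the former, so 73.6% of the calls were higher. Apoe, which encodes apolipoprotein E (chromosome 7, 19696109 to 19699188), rose from 39675 ± 5178 to 81193 ± 10544 normalised reads (SD, n = 3 each, limma log2 fold change 1.03, SE 0.12, adjusted p = 2.57e-04). Among the rises, 585 exceeded 3 on the log2 scale, 280 lay between 1 and 3, and 390 lay below 1. Among the falls, 64 exceeded 3 in size, 59 lay between 1 and 3, and 328 lay below 1. All 3 BODIPY-high libraries lay above all 3 BODIPY-low libraries in 2305 genes and below them in 1713, together 31.3% of the tested genes against 10% by chance. edgeR also called 1182 of the rises and 411 of the falls, and DESeq2 1235 and 449. Leaving out BODIPY-high replicate 3 lowered the rises to 662. The falls numbered 180 without BODIPY-low replicate 2, 151 without BODIPY-low replicate 3 and 219 without BODIPY-high replicate 3, and 760 with the replicate number as a block. With the mean level of the choroid plexus markers or of the neutrophil markers as a covariate, limma called 0 genes (679 and 1149 at an unadjusted p under 0.05), and these covariates had a squared correlation of 0.916 and 0.898 with the group.

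**Figure D1:**
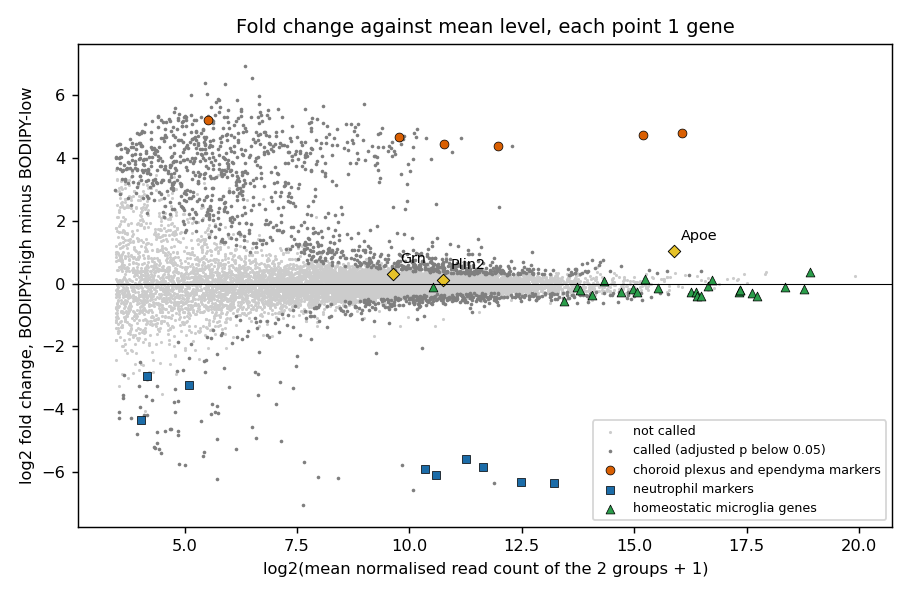
Each point is 1 of 12821 tested genes, with the log2 of its mean normalised read count plus 1 on the horizontal axis and its log2 fold change, BODIPY-high minus BODIPY-low, on the vertical axis, dark grey where limma called it and light grey where not, with Grn, Plin2 and Apoe as yellow diamonds. The 6 choroid plexus and ependyma markers (orange circles) lie between 4.39 and 5.23, the 9 neutrophil markers (blue squares) between -6.35 and -2.94, and the 25 homeostatic microglia genes (green triangles) between -0.56 and 0.38.

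Markers of the choroid plexus and ependyma rose in BODIPY-high libraries. All 6 tested markers passed (6 adjusted over the list alone), with a median log2 fold change of 4.71 (camera adjusted p = 1.65e-09, and adjusted p = 0.205 with an estimated correlation). Ttr, which encodes transthyretin and is made in bulk by choroid plexus epithelium (chromosome 18, 20665280 to 20674321), rose from 3428 ± 2876 to 71489 ± 14632 normalised reads (SD, n = 3 each, limma log2 fold change 4.74, SE 0.47, adjusted p = 1.28e-04). Enpp2, which encodes autotaxin (chromosome 15, 54838901 to 54952892), rose from 5489.8 ± 4351 to 132138 ± 46263 (log2 fold change 4.82, SE 0.45, adjusted p = 7.94e-05). Reads of the 6 markers made up 0.0339% ± 0.0263 of all reads in BODIPY-low and 0.768% ± 0.217 in BODIPY-high libraries (SD, n = 3 each), a ratio of 22.7 (exact two-sided permutation p = 0.1, the smallest possible). Without BODIPY-low replicate 1 the BODIPY-low mean was 0.0191% and the ratio 40.2. The lowest share was that of BODIPY-low replicate 2, at 0.0131% (interval 0.0127 to 0.0136), and the highest that of BODIPY-high replicate 3, at 0.921% (0.918 to 0.925).

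The 10 largest rises by the naming rule were those of Wdr72, Cdh3, Scara5, Bhmt, Cndp1, Bmp4, Vldlr, Dmrt3, Nrbp2 and Islr, and they stood beside the rise of the choroid plexus markers (median 4.71). Scara5, a ferritin receptor, Bhmt, the betaine-homocysteine methyltransferase, and Bmp4, a bone morphogenetic protein, had no read in the BODIPY-low group. With reads pooled over each group, they were at least 82.4-fold, 126-fold and 70.1-fold higher in BODIPY-high libraries. These bounds do not hold for each library. BODIPY-high values of Bhmt were 80.1, 27.2 and 246 normalised reads in replicates 1, 2 and 3, and those of Bmp4 were 45.2, 51.0 and 111. Wdr72 had 1 read in BODIPY-low and 526 in BODIPY-high libraries (ratio 475, interval 84.8 to 18786), and Cndp1, a carnosine dipeptidase, had 1 and 293 (ratio 264, interval 47.1 to 10480). Cdh3, or P-cadherin, had 3 and 594 (ratio 179, interval 60.9 to 869), and Dmrt3 had 3 and 342 (ratio 103, interval 34.9 to 501). Vldlr, the very low density lipoprotein receptor, rose from 4.17 ± 6.32 to 195 ± 73.8 (log2 fold change 5.99), Nrbp2 from 1.85 ± 1.73 to 139 ± 29.2 (5.85) and Islr from 1.52 ± 2.64 to 105 ± 39.9 (5.84), with adjusted p of 8.84e-04, 2.67e-04 and 8.58e-04. Exons of Islr overlap those of Islr2 on the same strand.

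**Figure D2:**
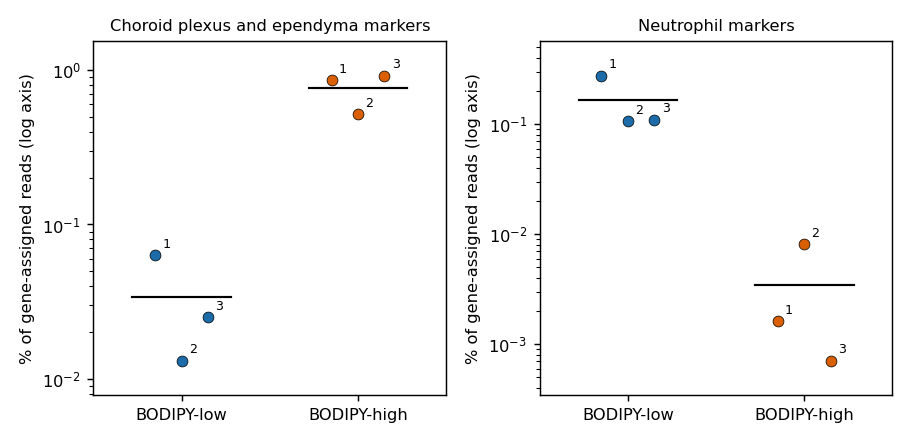
Share of gene-assigned reads, in percent on a log axis, taken by 6 choroid plexus and ependyma markers (left) and by 9 neutrophil markers (right) in BODIPY-low and BODIPY-high libraries, where each point is 1 library with its replicate number and black lines are group means. The choroid plexus markers averaged 0.0339% in BODIPY-low and 0.768% in BODIPY-high libraries, and the neutrophil markers 0.165% and 0.00348%.

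Neutrophil genes fell in BODIPY-high libraries. Of 9 tested markers 8 fell (9 adjusted over the list alone), with a median log2 fold change of -5.85, also with 1 member set at its floor (camera adjusted p = 2.46e-10, and adjusted p = 0.205 with an estimated correlation). Ngp, neutrophilic granule protein, fell from 18608 ± 11233 to 328 ± 374 normalised reads (SD, n = 3 each, limma log2 fold change -6.35, SE 0.68, adjusted p = 1.85e-04), and Ltf, which encodes lactoferrin, fell from 11190.1 ± 6814 to 205 ± 243 (-6.34, SE 0.69, adjusted p = 2.08e-04). The share of reads from the 9 markers was 0.165% ± 0.0971 in BODIPY-low and 0.00348% ± 0.00403 in BODIPY-high libraries (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest possible). Without BODIPY-low replicate 1 the BODIPY-low mean was 0.109%, and without BODIPY-high replicate 2 the BODIPY-high mean was 0.00117%. The remaining 8 of the 10 largest falls were those of Itgb2l (-7.05), Cd177 (-6.57), Chil3 (-6.35), Trem3, Hp (-6.19), Serpinb1a (-6.17), Lcn2 (-6.09) and Camp (-5.91), with adjusted p between 5.14e-05 and 0.00176. Camp lost its call with the robust variance model (adjusted p = 0.0681). Trem3 had 291 reads in BODIPY-low and 1 in BODIPY-high libraries (ratio 322, interval 57.4 to 12779). Of 7 tested monocyte genes 5 fell (6 adjusted over the list alone), with a median of -5.02 (camera adjusted p = 1.75e-06, and adjusted p = 0.205 with an estimated correlation). Chil3, a chitinase-like protein, fell from 7409.8 ± 3306 to 172 ± 222 and Hp, which encodes haptoglobin, from 655 ± 387 to 18.8 ± 27.9.

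Part of the tested genes of mitochondrial respiration rose in BODIPY-high libraries. Of 91 tested nuclear genes of the respiratory chain 37 rose and the other 54 did not pass (55 rose when adjusted over the list alone), with a median log2 fold change of 0.50 (camera adjusted p = 2.94e-16, and adjusted p = 0.290 with an estimated correlation). Atp5g1, which encodes a subunit of the ATP synthase ring, rose from 889.6 ± 199 to 2012 ± 312 normalised reads (SD, n = 3 each, limma log2 fold change 1.19, SE 0.17, adjusted p = 0.00101). Cox8b, Cox6b2 and Cox7a1, subunit forms of cytochrome oxidase best known from muscle or testis, rose from 3.98 ± 4.69 to 82.3 ± 18.4, from 13.8 ± 6.04 to 92.3 ± 23.6 and from 3.16 ± 1.26 to 22.7 ± 7.20. Cox7a1 lost its call without BODIPY-low replicate 2 or 3 or BODIPY-high replicate 1 or 2 (adjusted p between 0.0727 and 0.121) and with the replicate number as a block (0.0528). Against the mean of the BODIPY-low libraries, the respiratory chain list averaged 0.46, 0.62 and 0.65 in BODIPY-high replicates 1, 2 and 3, and 0.29, -0.27 and -0.03 in BODIPY-low replicates 1, 2 and 3. Of 22 fatty acid oxidation genes 12 rose (15 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 6.39e-08, and adjusted p = 0.205 with an estimated correlation). Acaa2, the thiolase of mitochondrial beta-oxidation, rose from 821 ± 70.4 to 2290.3 ± 362 (log2 fold change 1.47, SE 0.14, adjusted p = 7.94e-05), and Etfb, Eci1 and Etfa rose by 0.90, 0.76 and 0.73 on the log2 scale. Of 19 glycolysis genes 11 rose (12 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 2.53e-05, and adjusted p = 0.290 with an estimated correlation). Aldoa, an aldolase, rose from 15141 ± 283 to 25337 ± 1288 (log2 fold change 0.74, SE 0.08, adjusted p = 1.49e-04), Pgk1 by 0.72, Pkm by 0.70 and Pfkp, the platelet phosphofructokinase, by 3.50. Choroid plexus markers rose in the same libraries by a median of 4.71, and 1 called member each of the respiratory chain and glycolysis lists, Cox8b and Pfkp, rose by over 3.

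Lists of lipid synthesis and uptake moved in part. Of 20 genes of the liver X receptor and fatty acid synthesis list 4 rose (4 rose and 2 fell when adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.137, fry adjusted p = 0.00689). These were Apoe (1.03), Fads2, a fatty acid desaturase that rose from 31.5 ± 6.73 to 249 ± 66.2 (SD, n = 3 each, limma log2 fold change 2.93, SE 0.32, adjusted p = 2.08e-04), Elovl6, a fatty acid elongase (1.71, adjusted p = 0.0412), and Npc2, which carries cholesterol out of lysosomes (0.41, adjusted p = 0.0470). Of 22 cholesterol synthesis genes 3 rose (3 adjusted over the list alone), with a median of 0.05 (camera adjusted p = 0.577). Sqle, the squalene epoxidase, rose from 150.1 ± 1.35 to 310.1 ± 51.6 (log2 fold change 1.03, SE 0.20, adjusted p = 0.00736), Fdps by 0.52 and Hmgcs1 by 0.45. Among 13 genes of fatty acid uptake 3 rose and 1 fell (3 and 1 adjusted over the list alone), with a median of -0.03, a mean of 0.52 and camera's direction upward (adjusted p = 0.751). Vldlr (5.99), Fabp3 (1.66) and Slc27a1 (0.57) rose, and Cd36, a scavenger receptor for fatty acids, fell from 126 ± 22.4 to 39.9 ± 15.7 (-1.68, adjusted p = 0.0110). Choroid plexus markers rose in the same libraries by a median of 4.71. With 1 library left out, the calls of Elovl6, Npc2 and Fdps held only without BODIPY-low replicate 1 and that of Hmgcs1 only without BODIPY-high replicate 2 (adjusted p up to 0.140, 0.177, 0.134 and 0.159 otherwise). Slc27a1 was lost without BODIPY-low replicate 2 or 3 or BODIPY-high replicate 1 or 3 (up to 0.103), Fabp3 without BODIPY-high replicate 3 (0.0619) and Cd36 without BODIPY-low replicate 3 (0.0588).

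Some lysosomal, endosomal and autophagy genes rose in BODIPY-high libraries. Of 40 lysosomal genes 4 rose (6 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.0206, and adjusted p = 0.564 with an estimated correlation). Atp6v1a, a subunit of the proton pump, rose from 4469.6 ± 302 to 7338 ± 1260.3 (SD, n = 3 each, limma log2 fold change 0.70, SE 0.12, adjusted p = 0.00373), and Npc2, Glb1 and Lamp1 rose by 0.41, 0.31 and 0.29. Of 27 endosomal trafficking genes 3 rose (3 adjusted over the list alone), namely Rilp (1.47), Vps29 (0.41) and Rab7 (0.31), with a median of 0.12 (camera adjusted p = 0.0122, and adjusted p = 0.290 with an estimated correlation). Of 24 mTOR and autophagy genes 6 rose (7 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.0144, and adjusted p = 0.205 with an estimated correlation). Rragd, a GTPase that recruits mTOR to lysosomes, rose from 348 ± 66.7 to 766 ± 158 (log2 fold change 1.13, SE 0.20, adjusted p = 0.00389), Map1lc3a by 0.96, Sqstm1 by 0.44 and Gabarapl1 by 0.42. In these libraries choroid plexus markers rose by a median of 4.71. The lysosomal list lost its call without BODIPY-low replicate 2 or 3 or BODIPY-high replicate 1 (adjusted p = 0.0836, 0.0908 and 0.0851) and the endosomal list without BODIPY-high replicate 1 (0.0622). The lysosomal list also lost it with fry (0.132) and, like Glb1 and Lamp1, with the trend on transcript length and GC content removed (adjusted p = 0.0557, 0.0713 and 0.0627). With 1 library left out, Npc2, Lamp1 and Gabarapl1 held only without BODIPY-low replicate 1, and Glb1 and Rab7 only without BODIPY-high replicate 2 (adjusted p up to 0.177, 0.139, 0.104, 0.170 and 0.102 otherwise). Rilp failed without BODIPY-low replicate 2 or 3 or BODIPY-high replicate 1 or 3 (up to 0.0833) and Vps29 without replicate 2 or 3 of either group (up to 0.108).

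Some genes of homeostatic microglia fell in BODIPY-high libraries. Of 25 tested 5 fell (7 adjusted over the list alone), with a median of -0.20 (camera adjusted p = 1.30e-04, and adjusted p = 0.238 with an estimated correlation). Gpr34, a lysophosphatidylserine receptor, fell from 98376 ± 2209 to 74222 ± 3023 (SD, n = 3 each, limma log2 fold change -0.41, SE 0.08, adjusted p = 0.00623). Cx3cr1, the fractalkine receptor, fell by 0.39, Tgfbr1 fell by 0.38 and Mertk, a receptor for apoptotic cells, fell by 0.28, but with 1 library left out these calls held only without BODIPY-high replicate 1 (adjusted p up to 0.158, 0.0998 and 0.183 otherwise). Of 28 genes of disease-associated microglia 4 rose (7 rose and 1 fell when adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.137). These were Apoe (1.03), Cst7, which encodes cystatin F (1338 ± 411 to 2089 ± 64.2, log2 fold change 0.69, adjusted p = 0.0357), the lysozyme gene Lyz2 (0.43) and Timp2 (0.33). With 1 library left out, the call of Cst7 held only without BODIPY-low replicate 3 (adjusted p up to 0.105 otherwise), and those of Lyz2 and Timp2 were lost without BODIPY-low replicate 2 or 3 or BODIPY-high replicate 1 or 2 (up to 0.132 and 0.0938). Choroid plexus markers rose and neutrophil markers fell in the same libraries, with medians of 4.71 and -5.85.

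A few inflammatory and early response genes fell in BODIPY-high libraries. Of 23 cytokine and NF-kB genes 3 fell (6 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.00193, and adjusted p = 0.205 with an estimated correlation). Tlr2, a receptor for bacterial lipoproteins, fell from 13252 ± 931 to 9319.6 ± 546 (SD, n = 3 each, limma log2 fold change -0.51, SE 0.09, adjusted p = 0.00313), as did Rel (-0.45) and Cd14 (-0.36). Of 27 immediate early and heat shock genes 4 fell (5 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 9.73e-04, and adjusted p = 0.238 with an estimated correlation). Klf2, a transcription factor, fell from 1717 ± 306 to 839.5 ± 199.9 (log2 fold change -1.04, SE 0.18, adjusted p = 0.00359), as did Btg2 (-0.60), Jun (-0.53) and Klf6 (-0.49). Neutrophil markers fell in the same libraries, with a median of -5.85, and choroid plexus markers rose by a median of 4.71. In the leave-one-out fits Rel held only without BODIPY-high replicate 1 (adjusted p up to 0.115 otherwise). Jun failed without BODIPY-low replicate 2 or 3 or BODIPY-high replicate 1 (up to 0.117) and Cd14 without BODIPY-high replicate 3 (0.0523).

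A few cell cycle genes fell as well. Of 28 tested 3 fell (3 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 2.52e-04, and adjusted p = 0.323 with an estimated correlation). These were Mki67, a marker of dividing cells (-1.70, adjusted p = 0.0240), Ccnb2, a mitotic cyclin (-1.39, adjusted p = 0.0172), and Hmgb2 (-0.63, adjusted p = 0.0347). Of 23 genes of endoplasmic reticulum stress only Atf6, a sensor of unfolded proteins, fell (-0.35, adjusted p = 0.0332), with a list median of -0.11 (camera adjusted p = 0.0268, and adjusted p = 0.426 with an estimated correlation). Adjusted over the list alone limma called 0 of these (4 lower at an unadjusted p under 0.05, and over all genes 2 lower by edgeR and 2 by DESeq2). Neutrophil markers fell beside these lists, with a median of -5.85, and choroid plexus markers rose by a median of 4.71. The endoplasmic reticulum list lost its call without BODIPY-low replicate 1 or BODIPY-high replicate 2 or 3 (adjusted p = 0.275, 0.0938 and 0.0900) and with quantile scaling (0.0847). In the leave-one-out fits Atf6 held only without BODIPY-low replicate 1, Mki67 only without BODIPY-high replicate 2 and Hmgb2 only without BODIPY-low replicate 2 (up to 0.155, 0.0936 and 0.101 otherwise), and Ccnb2 failed without BODIPY-low replicate 1 or 3 or BODIPY-high replicate 3 (up to 0.0842).

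Some oxidative stress genes rose while Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell. Of 27 tested 8 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.00258, and adjusted p = 0.290 with an estimated correlation). Cybb fell from 1983 ± 559.8 to 496 ± 186 (SD, n = 3 each, limma log2 fold change -2.04, SE 0.28, adjusted p = 8.23e-04). The antioxidant enzymes Nqo1 (3.82, adjusted p = 0.00187), Gpx4 (0.69) and Prdx2 (0.67) rose. Choroid plexus markers rose in the same libraries by a median of 4.71, and neutrophil markers fell with a median of -5.85. Prdx2 lost its call without BODIPY-high replicate 3 (adjusted p = 0.0619) and Gpx4 without replicate 2 or 3 of either group (up to 0.0953).

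Some complement and phagocytosis genes rose and others fell. Of 17 complement genes 1 rose and 3 fell (2 and 4 adjusted over the list alone), with a median of 0.12, a mean of 0.18 and camera's direction downward (adjusted p = 0.529). C3, the central complement component, fell from 1000.0 ± 151 to 219.8 ± 74.0 (SD, n = 3 each, limma log2 fold change -2.22, SE 0.22, adjusted p = 1.35e-04), as did Itgam (-0.33), which encodes the CD11b used in the sort, and C3ar1 (-0.29), while Cd55, a brake on complement, rose (4.39, adjusted p = 4.72e-04). Of 26 phagocytosis receptors and partners 4 rose and 3 fell (4 and 5 adjusted over the list alone), with a median of -0.04, also with Tyro3 set at its floor, a mean of 0.28 and camera's direction downward (adjusted p = 0.560). Tyro3, a receptor tyrosine kinase, had 3 reads in BODIPY-low and 306 in BODIPY-high libraries (ratio 92.1, interval 31.2 to 449). Gulp1, an engulfment adaptor, rose by 4.84 and Mfge8, a bridge to apoptotic cells, by 0.78, and Cd36 fell (-1.68). Beside these rises and falls, choroid plexus markers rose by a median of 4.71 and neutrophil markers fell with a median of -5.85. Itgam lost its call without BODIPY-low replicate 2 or BODIPY-high replicate 3 (adjusted p = 0.0660 and 0.0761) and Cd36 without BODIPY-low replicate 3 (0.0588), and with 1 library left out C3ar1 held only without BODIPY-high replicate 1 (up to 0.191 otherwise).

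Interferon, antigen presentation and ribosomal protein genes gave few calls. Of 25 interferon response genes limma called 0, and 0 adjusted over the list alone (1 lower at an unadjusted p under 0.05, 0 by edgeR and 1 lower by DESeq2), with a median of -0.14 (camera adjusted p = 0.0803). Slfn2 had 1867 ± 386 and 1374 ± 132 normalised reads in BODIPY-low and BODIPY-high libraries (adjusted p = 0.0850) and Ifit2 had 570.2 ± 60.1 and 452 ± 59.5 (adjusted p = 0.207). With the replicate number as a block Slfn2 passed as lower (adjusted p = 0.0306). Of 22 antigen presentation genes only Psme1, a proteasome activator, rose (0.46, adjusted p = 0.0481), a call that with 1 library left out held only without BODIPY-high replicate 1 (up to 0.187 otherwise). Adjusted over the list alone limma called 0 of these 22 (2 higher and 7 lower at an unadjusted p under 0.05, and over all genes 1 lower by edgeR and 1 higher and 2 lower by DESeq2), and their median was -0.10 (camera adjusted p = 0.137). Of 79 cytosolic ribosomal protein genes limma called 0, and 0 adjusted over the list alone (1 higher at an unadjusted p under 0.05, 0 by edgeR and 0 by DESeq2), with a median of 0.12 (camera adjusted p = 0.181). Rpl4 had 4607 ± 461 and 5604 ± 744 normalised reads (adjusted p = 0.142) and Rpl6 had 1297 ± 215 and 1652 ± 300.4 (adjusted p = 0.200).

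Some markers of other brain cells also moved, beside choroid plexus markers that rose in the same libraries by a median of 4.71. Of 12 astrocyte genes 5 rose (7 adjusted over the list alone), with a median of 1.19 (camera adjusted p = 2.28e-05, and adjusted p = 0.205 with an estimated correlation). Clu, which encodes clusterin, rose from 479 ± 225 to 9528 ± 2466 (SD, n = 3 each, limma log2 fold change 4.39, SE 0.30, adjusted p = 2.06e-05), and the glutamate transporter gene Slc1a3 stood at 7033 ± 601 and 7617 ± 1159 (adjusted p = 0.595). Of 9 neuronal genes 2 rose (3 adjusted over the list alone), with a median of 1.37, also with 1 member set at its floor (camera adjusted p = 0.00726, 0.0646 with quantile scaling, and adjusted p = 0.205 with an estimated correlation). The most abundant of these, Prox1 and Camk2a, did not pass (-0.26 and 0.67, adjusted p = 0.620 and 0.281). Of 9 oligodendrocyte genes only Trf, which encodes transferrin, rose, from 78344 ± 1355 to 104775 ± 7271 (log2 fold change 0.42, adjusted p = 0.00771), and 4 rose when adjusted over the list alone (median 0.42, camera adjusted p = 0.00258, and adjusted p = 0.290 with an estimated correlation). Cnp of the same list stood at 2812 ± 224 and 3336 ± 387 (adjusted p = 0.185). Of 10 border macrophage genes 2 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 0.0612). The most abundant of these, Stab1 and Mrc1, did not pass (-0.06 and 0.55, adjusted p = 0.819 and 0.0563), though Mrc1 passed as higher with the replicate number as a block (adjusted p = 0.0285). Of 11 endothelial genes 1 rose (1 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.203), and Kdr (0.36) and Pecam1 (-0.05) did not pass (adjusted p = 0.180 and 0.915).

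The remaining cell type lists had under 5 tested genes and no list test, and their rises stood beside that of the choroid plexus markers (median 4.71). Among 3 oligodendrocyte precursor genes Pdgfra, a growth factor receptor, rose (4.01, adjusted p = 0.0177, but 0.0740 without BODIPY-high replicate 3) and Cspg4 fell (-2.68, adjusted p = 0.0488), 1 higher and 1 lower also when adjusted over the list alone. In the leave-one-out fits the call of Cspg4 held only without BODIPY-high replicate 2 (adjusted p up to 0.234 otherwise). Among 4 mural genes Vtn, which encodes vitronectin, rose from 13.5 ± 9.27 to 151 ± 46.3 (SD, n = 3 each, limma log2 fold change 3.53, adjusted p = 0.00115), Tagln did not pass (0.66, adjusted p = 0.456), and 2 mural genes rose when adjusted over the list alone. The 2 tested genes each of T and NK cells (Ccl5 and Cd4), B cells (Cd79b and Cd79a) and erythroid cells (Alas2 and Slc4a1) gave 0 calls by limma, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by edgeR and DESeq2. Log2 fold changes were 0.18 for Ccl5, 0.84 for Cd4, -0.26 for Cd79b, -0.90 for Cd79a, -0.04 for Alas2 and -1.60 for Slc4a1, with adjusted p from 0.482 to 0.990.

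Camera called 18 of 30 lists, 11 upward and 7 downward. With an estimated correlation camera called 0 of the 30 (7 at an unadjusted p under 0.05), the smallest adjusted p being 0.205, while fry called 15, of which 14 were among the 18. The 4 of the 18 that fry did not call were the lists of lysosome, oxidative stress, endoplasmic reticulum stress and cell cycle (adjusted p = 0.132, 0.0583, 0.211 and 0.0934). The list called by fry but not by camera was that of the liver X receptor and fatty acid synthesis (adjusted p = 0.00689 by fry and 0.137 by camera). With the trend on transcript length and GC content removed, Atf6, C3ar1, Cox7a1, Cspg4, Cst7, Cx3cr1, Fdps, Hmgb2, Mertk, Psme1, Rel, Slc27a1 and Tgfbr1 were among the named genes that lost the call (adjusted p between 0.0506 and 0.215). edgeR did not call C3ar1, Cst7, Elovl6, Glb1, Hmgcs1, Mertk, Npc2 or Psme1 (adjusted p between 0.0510 and 0.0678). Without the filter on low values C3ar1, Cspg4, Cx3cr1, Elovl6, Lamp1, Mertk and Npc2 lost the call (between 0.0517 and 0.0690), and with quantile scaling Cox7a1, Elovl6, Jun, Mertk, Psme1 and Rilp did (between 0.0565 and 0.193). Psme1 also lost it with TMM scaling, with the same total per library, with a pseudocount of 0.5 and with a filter at a mean of 50 (between 0.0505 and 0.0550). So did Npc2 and Lamp1 with TMM scaling (0.0522 and 0.0572), Hmgcs1 with the same total (0.0594), Cspg4 with that pseudocount or filter (0.0536 and 0.0724), and Npc2 with that filter (0.0518). Of the 91 called genes that the naming rule took, 56 kept the call whichever single library was left out. Exons of genes on the other strand overlap those of Aldoa, Pfkp, Sqstm1, Enpp2, Jun and Prdx2 and, among further named genes, those of Bhmt, Bmp4, Cndp1, Nrbp2, Cd55, Cx3cr1, Fabp3, Lamp1, Vps29, Psme1, Elovl6, Gabarapl1, Hmgcs1, Rab7 and Pdgfra, and reads of such pairs cannot be told apart in these libraries.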

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

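The 5 added alternatives (the marker covariates, the removal of the length and GC trend for genes and for lists, and camera without genes changed by over 3) were chosen after seeing the data. The pseudocount, the filter, the 3 scalings, the robust variance model, edgeR, DESeq2 and the removal of the length and GC trend left both counts of genes within 1.5 times of 1255 higher and 451 lower. With the numbers of the replicates as a replicate block, 1451 genes were higher and 760 lower. Without replicates 1, 2 and 3 in turn that fit called 1117, 829 and 178 genes lower and, without replicate 3, 767 higher. Fits without a replicate number have very few libraries for a block and a group term. Their spread rests mostly on the variance shared across genes, so these counts say little about robustness. Deviations from the group means correlated by 0.11, 0.14 and 0.07 across genes, which are not independent replicates, between same-numbered libraries, and each BODIPY-low library correlated best with its own number. Since the labels do not say that numbers share mice, the unpaired fit set beforehand was kept. These correlations are what low and high libraries from a shared pool would give, but they are small and do not settle it. The fall count was also 763 with array weights, 723 by DESeq2 with the replicate block and 822 at an adjusted p below 0.1, the last because the threshold was wider. Leaving out 1 library gave 662 to 1309 genes higher and 151 to 527 lower, with fewer samples, and 17 to 19 lists. With the choroid marker covariate limma called 0 genes higher and 0 lower, and with the neutrophil marker covariate 0 and 0 (679 and 1149 at an unadjusted p under 0.05), these covariates being nearly collinear with the group (squared correlation 0.916 and 0.898). Lists called by camera went from 18 to 0 with an estimated correlation (7 at an unadjusted p under 0.05) and to 15 with fry. Over all alternatives the named genes kept direction and side of the threshold in 2541 cases, lost the call in 389, gained it in 23 and reversed in 29. The lists kept theirs in 487, lost it in 32 and gained it in 17. Under the choroid marker covariate the reversed log2 fold changes were those of Atp5g1 (-0.053), Btg2 (0.34), Cox8b (-1.57), Cst7 (-0.25), Elovl6 (-0.018), Etfa (-0.0015), Etfb (-0.50), Gpx4 (-0.44), Gulp1 (-0.24), Jun (0.44), Lyz2 (-0.067), Npc2 (-0.40), Nqo1 (-0.63), Pdgfra (-3.92), Pfkp (-0.0070), Prdx2 (-0.25), Slc27a1 (-0.093), Ttr (-0.32) and Vtn (-0.26). Under the neutrophil marker covariate they were those of Camp (2.05), Cd177 (1.30), Chil3 (0.63), Hmgb2 (0.29), Hmgcs1 (-0.32), Hp (1.96), Ltf (0.020), Mki67 (1.06) and Rragd (-0.21). Ttr is a member of the choroid covariate, and Camp and Ltf are members of the neutrophil one. Adjusting a gene for a mean that contains it removes its own group difference, so the reversals of Ttr, Camp and Ltf carry no information. The signs of the other reversed values cannot be read either, because the covariates are nearly collinear with the group. By limma, Pdgfra had an adjusted p of 0.913 with the choroid covariate and Hp 0.728 with the neutrophil one. Alas2 reversed to 2.75 in the replicate block fit without replicate 1. Grn passed under no alternative, with adjusted p from 0.065 to 0.99. For each of these changes the cause was not tested, except where stated. Of simulated genes changed 1.5-fold limma recovered 32%, so changes of that size are often missed at this depth and number of libraries.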

Other observations

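These gene groups were chosen after their values were seen. Toll-like receptors, which sense microbial products, were lower in BODIPY-high libraries in 7 of 12 tested cases by limma, with a median log2 fold change of -0.54, and 7, 7 and 5 were lower with TMM, total and quantile scaling. Their count was 4 without BODIPY-low replicate 2, BODIPY-low replicate 3 or BODIPY-high replicate 3. Tlr3 fell from 4629 ± 216 to 3157 ± 265 normalised reads (SD, n = 3 each, log2 fold change -0.55, limma adjusted p = 0.00313), as did Tlr4 (-0.53), Tlr2 (-0.51) and Tlr7 (-0.45). Neutrophil and monocyte markers fell in the same libraries, with medians of -5.85 and -5.02, and choroid plexus markers rose by a median of 4.71. Ptprc, which encodes CD45, was also lower (-0.43, limma adjusted p = 0.0392). With 1 library left out, Ptprc passed only without BODIPY-high replicate 1 (adjusted p up to 0.132 otherwise) and Tlr4 only without BODIPY-high replicate 1 or BODIPY-low replicate 2 (up to 0.0906 otherwise). Class II antigen presentation genes did not pass, H2-Aa, H2-Ab1, H2-Eb1 and Cd74 having log2 fold changes of -1.35, -1.14, -1.68 and -0.91 (limma adjusted p = 0.0904, 0.0822, 0.0755 and 0.129). In the same order, edgeR gave adjusted p of 0.154, 0.138, 0.135 and 0.205, and DESeq2 0.356, 0.339, 0.330 and 0.446. Without BODIPY-high replicate 3 all 4 passed as lower by limma (adjusted p = 0.0221, 0.0176, 0.0202 and 0.0201), and H2-Eb1 did so without BODIPY-high replicate 1 as well (0.0450).

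Further genes were also chosen after their values were seen. Ptgds, a prostaglandin D synthase abundant in choroid plexus and meninges, rose from 102 ± 42.9 to 2535 ± 858 (SD, n = 3 each, log2 fold change 4.64, limma adjusted p = 2.06e-05). Cfap genes, which encode proteins of cilia, were higher in 5 of 12 tested cases, with a median of 2.09 and a range of -0.46 to 5.55, beside choroid plexus and ependyma markers that rose by a median of 4.71. Mpo, myeloperoxidase of neutrophil granules, fell from 101 ± 98.3 to 1.58 ± 1.09, and Elane, neutrophil elastase, was lower as well. Cat, which encodes catalase, rose by 0.48. Hspa1a, a heat shock gene, stood at 2439 and 2147 normalised reads in replicate 1 of BODIPY-low and BODIPY-high, against 193 to 285 in the other libraries. It was thus high in both libraries with the number 1, as libraries from a shared pool would give, which was not tested.

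Of the tests that follow, the removal of the length and GC trend and the use of the interval for the respiratory chain genes were chosen after the result was seen. Choroid plexus markers were higher in BODIPY-high libraries by a median of 4.71. A second list of 15 choroid epithelium genes, written before their values were seen and sharing no gene with the other lists, was higher in 100% of cases (median 4.36, range 3.94 to 4.70), as RNA from choroid plexus cells in the BODIPY-high libraries would give, although the CD11b and CD45 gate should remove such cells. Otx2 and Aqp1 of this list reached 954 ± 255 and 536 ± 82.7 normalised reads (SD, n = 3 each), and 13 of the 15 had a mean of at least 10 in BODIPY-low libraries too. Contact with or uptake of such cells, or expression by BODIPY-high microglia themselves, may stand behind the same values and was not tested, so the source stays a hypothesis.

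Neutrophil markers were lower in BODIPY-high libraries, by a median of -5.85. If RNA from neutrophils in the BODIPY-low libraries were the source, at least 80% of a second neutrophil list written before its values were seen should have been lower, and under 50% if not. The share called lower was 53.8%, or 7 of 13 tested genes. All 13 had negative log2 fold changes (median -2.36, range -4.06 to -0.11). Csf3r had the smallest fall, at 20635 ± 2831 and 19141 ± 3473 normalised reads (SD, n = 3 each, log2 fold change -0.11). Csf3r was abundant in all 6 libraries and may be expressed by microglia, which keeps the question open. RNA from neutrophils, which the CD45 gate should remove, and a difference in the microglia themselves cannot be told apart here.

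Of 91 respiratory chain genes 37 were higher in BODIPY-high libraries, and the list had a median log2 fold change of 0.50. Transcript length and GC content do not account for the whole shift, since 0% of 10000 lists matched on length, GC content and mean level reached that median (highest 0.23), and it stayed at 0.40 with 38 genes called after the trend was removed. RNA from choroid plexus cells was tested by the order of the 3 BODIPY-high libraries, which was that of Ttr in 10.8% of the called genes, or 4 of 37, against 16.7% by chance and 55.6% of the 585 genes that rose by over 3. That value met the bound of at most 17% written before. Its exact interval of 3.03% to 25.4% reaches above it. The demand that the interval clear the bound was added after the value was seen. The interval also treats genes as independent, which they are not (estimated correlation 0.53), so it cannot decide the question. The order of Ttr was the mark of a gene made only by choroid plexus cells. Atp5g1 had a mean of 889.6 normalised reads in BODIPY-low libraries, so an added share need not impose that order. A share of choroid plexus RNA and a higher level in BODIPY-high microglia therefore cannot be told apart for these genes, because only 3 libraries can be ordered and the group and the markers are nearly collinear (squared correlation 0.916).

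The 6 libraries can be split into 3 and 3 in 10 ways, which are too few for a share under 0.05. The real split gave 1706 genes and the highest other split 0 by limma, so 1 of the 10 splits had as many (620 was the highest count at an unadjusted p under 0.05 among the others, against 3475). Every other split has libraries of both groups on both sides, so the group difference enters its residual spread and few calls could come out. The contrast therefore does not show how many calls would arise without a group difference.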
